A study of Mus musculus with 21 samples.

How the data were processed

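Gene expression was measured on Affymetrix Mouse Genome arrays from small intestine of mice, in 20 samples of sorted TdTomato-positive cells and 1 sample of whole intestine. Per the labels, sorted cells were parted by CD24 into a low and a high fraction, and RNA was extracted with an Ambion kit, amplified from 0.8 ng of total RNA with the GeneChip Pico kit and labelled with biotin. The deposited values are signal intensity per probe set, 45101 probe sets for each of 21 arrays, made by the authors with MAS5 per the submitters' processing notes, which do not give its version. The intensity values deposited were linear, and the mean over all probe sets, leaving out the lowest and highest 2 percent, was 500 on every array, the scaling that MAS5 applies. The deposited table held no detection calls, so signal and background were not separated for weak probe sets, and the fold change of a dim gene is limited by that. The table gave no coordinates of the probe sets.

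The labels place the 20 sorted samples in 10 groups of 2, with 2 fractions and 5 conditions, and this grouping was used as given. Whole intestine, whose cell type label reads villi, was kept out of every test. All 21 columns were used, and 0 pairs of arrays held identical values. The median signal of the sorted arrays ran from 101 to 158, and the 2 arrays of a group correlated at 0.942 to 0.985 across genes, which are not independent replicates. For arrays, depth is not counted, and their number limits the precision.

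Signals were transformed as log2(signal + 16) with the scaling the authors left. Of the probe sets, 34958 carried 1 gene symbol, 932 several and 9211 none, and only the first were used, covering 18194 genes. Probe sets were kept when above the median of their array in at least 2 of the 20 arrays, which left 22531, and each gene was represented by the kept probe set with the highest mean, giving 11854 genes. Of these, 5927 had more than 1 kept probe set, and 1202 were read through a probe set type that can match several transcripts or related genes. A level below 7.25 on this scale lies in the lower part of the arrays.

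Groups were compared with limma 3.58.1 in R 4.3.3, with a mean for each of the 10 groups, 10 residual degrees of freedom, moderated variances that follow the mean level, and the Benjamini-Hochberg adjustment over the genes of each comparison at 0.05. The 14 comparisons were CD24hi against CD24lo in untreated mice and averaged over the 5 conditions, each of 4 treatments against untreated in each fraction, and for each treatment the difference between its effects in the 2 fractions. Tests were two-sided. Where 1 array of a group was left out, the lone array was assumed to vary like the other groups. The tests of 25 gene lists used camera from limma, with a preset correlation between genes of 0.01 and, as an alternative, the correlation estimated from the data, adjusted over the lists of 1 comparison. A list count is the number of members past the threshold after adjustment over all genes, and beside it the number adjusted over the list alone.

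The groups, tests, gene lists, comparisons and the rule for which genes are named were fixed before the data were examined. That rule names in each comparison 12 genes whatever their result, Bhlha15, Cd24a, Lgr5, Atoh1, Lyz1, Muc2, Chga, Dclk1, Olfm4, Mki67, Cdkn1a and Hes1, with Notch1 added for NICD. It adds up to 4 members of each list past the threshold with the largest change, and the 5 higher and 5 lower genes with the largest change whose compared arrays did not overlap. The text may name fewer, in that order, and Erdr1 and Gkn1 were also singled out after their values were seen because they kept their calls without any 1 array. Genes of the second lists in the closing section were likewise named after their values were seen.

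Alternatives were a pseudocount of 1 or 64, quantile normalization, centring on the 75th percentile, no filter or a stricter one (above the 60th percentile in at least 4 arrays), the mean of a gene's probe sets, moderation without the trend or with robust settings, replicate number as a block, leaving out each array of the groups compared, and a fit to the groups compared alone. Chosen after seeing the data were fits without the array that stood apart, the average over conditions without NICD, list results without each array in turn, and the second lists in CD24hi cells after doxorubicin and with NICD and of T cell genes after Lgr5 ablation. Replicate numbers were not used as pairs, because the residuals of arrays sharing a number did not correlate in 1 direction across genes.

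The procedure was run on 11854 simulated independent genes in the same groups. For irradiation in CD24lo cells it recovered 37.3%, 85.1% and 100% of genes changed by 1, 2 and 3 on the log2 scale. Of 154 calls 6 were false. It recovered 95.5% of genes changed by 1 for the average over conditions and 8.96% for the difference between fractions. For 2 the latter gave 71.6%. Limma's camera called the shifted list and 0 of 24 others, leaving genes that move together untested.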

Results

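Gene expression was measured in 21 samples of mouse small intestine, each on its own Affymetrix array, and 20 of them were sorted cells. The sorted cells carried TdTomato, a red fluorescent protein that per the labels marked Mist1-positive cells, and flow cytometry parted them into a CD24lo and a CD24hi fraction. Mist1 is the protein of Bhlha15, a transcription factor of secretory cells, and CD24 is a surface protein that is abundant on Paneth cells. Each fraction came from 5 conditions with 2 arrays apiece. These were untreated mice, mice whose Lgr5-expressing cells had been ablated, mice irradiated with 10 Gy, mice given doxorubicin (a drug that damages DNA), and mice with NICD, a name commonly used for the intracellular domain of a Notch receptor, which the labels do not spell out. The last sample was whole intestine without a replicate and entered no test. The labels do not state whether the 2 replicates of a group came from separate animals, so every p-value here measures only the spread between these samples. The median signal of the 20 sorted arrays ranged from 101 to 158, and the number of arrays limits the precision. On the first principal component, CD24lo arrays lay between -65.4 and -8.82 and CD24hi arrays between 15.6 and 46.5. Replicate 2 of CD24hi NICD stood apart in its control probes, with a cre spike-in signal of 75343 against 22819 to 48833 on the other 19 arrays and a 3' to 5' actin ratio of 1.03 against 1.30 to 1.58. Values below are differences of log2(signal + 16) ± SE with n = 2 arrays per group unless another n is given, and p-values are adjusted over all genes tested. Folds of dim genes are understated on this scale.

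In untreated mice, genes of intestinal stem cells were higher in CD24hi than in CD24lo cells. Over all genes 15 of 16 members of the stem cell list were higher (16 adjusted over the list alone), with a median difference of 1.34. Lgr5, a receptor that marks stem cells, was higher by 2.54 ± 0.56, adjusted p = 0.0058, and Sox9, a transcription factor, by 2.30 ± 0.37. Targets of Wnt signalling went the same way in 12 of 15 members (13 adjusted over the list alone, median 1.47). Ephb3, a receptor that positions cells along the crypt, led at 3.18 ± 0.43. Ascl2, Axin2, Lgr5, Rnf43, Sox9 and Znrf3 are in both lists throughout. Paneth cell genes were higher in 7 of 14 members (8 adjusted over the list alone; median 0.93), among them Wnt3, a Wnt ligand made by Paneth cells, at 2.93 ± 0.53, and Habp2 at 2.62 ± 0.34. Tuft cell genes were higher in 5 of 11 members (7 adjusted over the list alone; median 1.37), with Sh2d6 at 3.62 ± 0.51 and Dclk1, a kinase widely used as a tuft cell marker, at 2.78 ± 0.45. Another probe set of Dclk1 gave 0.94, adjusted p = 0.219. Bhlha15, the gene behind the reporter, was higher by 2.10 ± 0.26, adjusted p = 6.57e-05. Cd24a, the sorting marker gene and 1 of the 7 Paneth genes, was higher by 1.14 ± 0.18. The stem cell list test gave adjusted p = 8.17e-12 with the preset correlation of camera, the Wnt list 1.36e-08, the Paneth list 2.44e-05 and the tuft list 1.27e-05, and each gave adjusted p = 0.113 with an estimated correlation. Without untreated CD24hi replicate 1, fewer stem cell, Wnt and tuft genes passed, and Lgr5 lost its call.

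Genes of absorptive enterocytes were lower in untreated CD24hi cells, 17 of 20 over all genes and 19 adjusted over the list alone, with a median of -2.20. Lct, the gene of the milk sugar enzyme lactase, differed by -3.51 ± 0.48, adjusted p = 0.000137. Interferon-induced genes were lower in 14 of 21 members (15 adjusted over the list alone; median -1.11), with the antiviral GTPase gene Mx1 at -2.65 ± 0.33. Goblet cell genes were lower in 7 of 20 members (7 lower and 1 higher adjusted over the list alone; median -0.40), among them Capn9 at -2.38 ± 0.20, Clca1, a protein secreted with mucus, at -2.24 ± 0.18, and Bcas1 at -2.22 ± 0.20. Muc2, a mucin, differed by -0.28 ± 0.26 and the lysozyme gene Lyz1 by 0.03 ± 0.28, both near the top of the scale and short of the threshold. The largest negative differences of all were Ido1, an enzyme that degrades tryptophan, at -4.48 ± 0.43, Gsta4, a glutathione transferase, at -4.36 ± 0.40, and Enpp3 at -3.98 ± 0.23. The list tests gave adjusted p = 9.23e-14 for enterocytes, 1.32e-10 for interferon and 0.000374 for goblet cells, against adjusted p = 0.156, 0.113 and 0.495 with an estimated correlation. The list of pan-epithelial genes, which any epithelial cell expresses, had a median of -0.35 and adjusted p = 0.0119, which became 0.0593 without untreated CD24lo replicate 2 and 0.0835 without untreated CD24hi replicate 1, and adjusted p = 0.277 with an estimated correlation. Olfm4 was higher by 0.98 ± 0.31, adjusted p = 0.0404, which became 0.1 without untreated CD24lo replicate 1, 0.165 without untreated CD24lo replicate 2, 0.153 without untreated CD24hi replicate 1 and 0.14 without untreated CD24hi replicate 2. Atoh1 differed by -0.07 ± 0.20, Chga by -0.40 ± 0.65, Mki67 by -0.16 ± 0.31, Cdkn1a by -0.86 ± 0.29 and Hes1 by 0.17 ± 0.34, short of the threshold. In all, 1704 genes differed, 890 higher and 814 lower in CD24hi cells. The excess of higher genes depended on the scaling, with 760 higher and 836 lower after quantile normalization and 744 higher and 967 lower after 75th percentile centring. Leave-one-out fits with limma called 868 genes without untreated CD24lo replicate 1 (9 enterocyte and 9 interferon genes) and 945 without untreated CD24hi replicate 1 (9 interferon genes). It called 947 without untreated CD24hi replicate 2 (8 enterocyte genes).

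Averaged over the 5 conditions, with 10 arrays per fraction, all 16 measured stem cell genes were higher in CD24hi cells, as were 10 of 11 tuft, 12 of 14 Paneth and 12 of 15 Wnt target genes, with the same counts adjusted over the list alone. Lgr5 was higher by 3.15 ± 0.25, adjusted p = 4.05e-08, Dclk1 by 3.49 ± 0.20 and Bhlha15 by 2.24 ± 0.12. All 20 enterocyte genes and 18 of 21 interferon genes were lower, again with the same counts adjusted over the list alone. Enteroendocrine genes, which mark hormone-secreting cells, were higher in 16 and lower in 2 of 24 members, also adjusted over the list alone. The hormone gene Sst (somatostatin) was higher by 3.09 ± 0.24 and Nts (neurotensin) was lower, at -3.02 ± 0.21. Among reserve stem cell genes 4 of 5 were higher, also adjusted over the list alone, with Lrig1, a brake on growth factor receptors, at 1.24 ± 0.10. Immediate early genes, which respond within minutes to stimuli including tissue dissociation, were higher in 6 of 13 members (7 adjusted over the list alone), the nuclear receptor gene Nr4a1 most, at 2.37 ± 0.17. The largest differences included Smim38 at 4.71 ± 0.22 and Samd5 at 4.17 ± 0.35 on the higher side, and Gsta4 at -3.48 ± 0.18 and Fam3b at -3.26 ± 0.15 on the lower side. Cd24a, in the Paneth list too, was higher by 1.01 ± 0.08, adjusted p = 3.08e-08. Atoh1 was lower, at -0.23 ± 0.09, adjusted p = 0.0449, which became 0.0664 without untreated CD24lo replicate 1, 0.0648 without untreated CD24lo replicate 2, 0.0868 without untreated CD24hi replicate 1, 0.106 without Lgr5-ablated CD24lo replicate 1, 0.0868 without Lgr5-ablated CD24hi replicate 2, 0.11 without irradiated CD24lo replicate 1, 0.0975 without irradiated CD24hi replicate 2, 0.0601 without NICD CD24lo replicate 1, 0.0721 without NICD CD24lo replicate 2, 0.0846 without NICD CD24hi replicate 2, 0.0724 without doxorubicin CD24lo replicate 1, 0.0675 without doxorubicin CD24lo replicate 2, 0.0642 without doxorubicin CD24hi replicate 1 and 0.08 without doxorubicin CD24hi replicate 2. Olfm4 was higher by 1.28 ± 0.14, adjusted p = 1.09e-06. Hes1 was higher by 0.43 ± 0.15, adjusted p = 0.0261, which became 0.0592 without Lgr5-ablated CD24hi replicate 1, 0.0555 without irradiated CD24lo replicate 2, 0.0662 without irradiated CD24hi replicate 1, 0.0524 without NICD CD24lo replicate 1, 0.0628 without doxorubicin CD24lo replicate 2 and 0.0533 without doxorubicin CD24hi replicate 2. Lyz1 differed by 0.09 ± 0.13, Muc2 by -0.06 ± 0.12, Chga by 0.31 ± 0.29, Mki67 by -0.03 ± 0.14 and Cdkn1a by 0.17 ± 0.13, short of the threshold. Another Lyz1 probe set passed, at 0.69, adjusted p = 0.00869. Of 5529 genes past the threshold, 3249 were higher and 2280 lower. Quantile normalization gave 2994 higher and 2490 lower, and 75th percentile centring 2694 higher and 2679 lower. Of 96 named genes past the threshold, 71 had the same sign in each condition, and 12 lost their call when the NICD condition was left out, among them Atoh1 at -0.021, adjusted p = 0.881, and Hes1 at 0.31, adjusted p = 0.169. Without NICD, enteroendocrine genes were higher in 13 and lower in 4 members, tuft genes higher in 8, Paneth genes higher in 11 and interferon genes lower in 16. Tested as lists, these gave adjusted p = 2.42e-09 for stem cell, 1.26e-06 for tuft, 1.22e-06 for Paneth, 1.22e-06 for Wnt and 2.42e-09 for interferon genes, each with adjusted p = 0.127 with an estimated correlation. They gave 6.13e-12 for enterocyte and 0.00424 for enteroendocrine genes, with adjusted p = 0.207 and 0.595 with an estimated correlation, while the reserve stem cell (0.0692) and immediate early (0.119) lists did not pass.

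**Figure D1:**
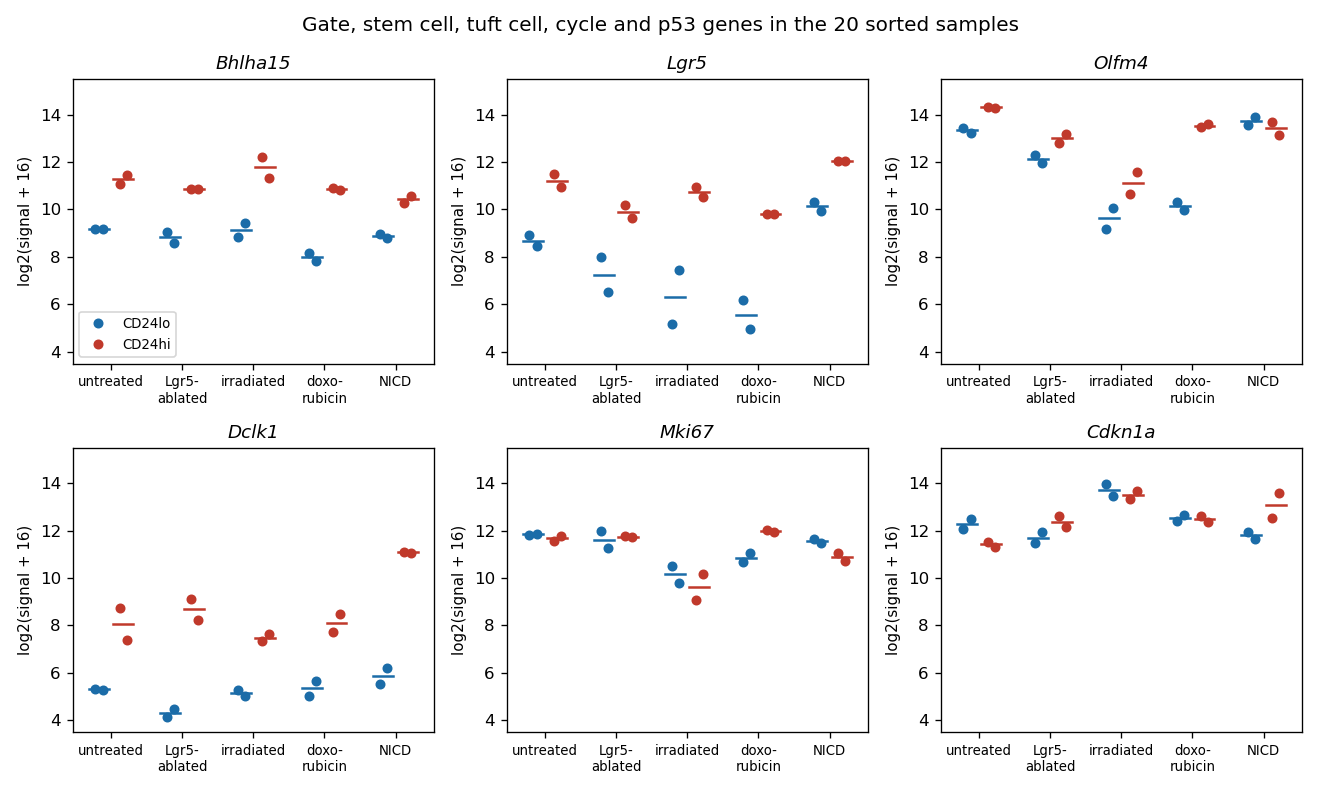
Signal of Bhlha15, Lgr5, Olfm4, Dclk1, Mki67 and Cdkn1a in each sorted array, as log2(signal + 16) on the vertical axis against the 5 conditions for CD24lo and CD24hi cells, with each point an array and each bar the mean of 2. Mean Bhlha15 was 9.17 ± 0.01 (SD) in untreated CD24lo and 11.27 ± 0.26 in untreated CD24hi cells, and mean Olfm4 was 9.62 ± 0.64 in irradiated CD24lo against 13.33 ± 0.15 in untreated CD24lo cells.

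Lgr5-ablated mice were labelled DT, and no group had DT without ablation, so effects of the 2 cannot be told apart. Lgr5 itself measured 8.90 and 8.44 in untreated and 7.98 and 6.53 in ablated CD24lo arrays, a difference of -1.42 ± 0.56, adjusted p = 0.585, short of the threshold, while the other Lgr5 probe set gave -0.00013, adjusted p = 1. In CD24lo cells, genes of MHC class II, which present peptides to helper T cells, rose in 2 of 6 members (6 adjusted over the list alone; median 1.47), with H2-Eb1 at 1.97 ± 0.23, adjusted p = 0.00089. The chemokine gene Cxcl9, which interferon gamma induces, rose by 3.61 ± 0.47. Paneth list genes fell in 3 of 14 members (6 adjusted over the list alone; median -0.52), with Clps, a cofactor of pancreatic lipase, at -2.13 ± 0.27. Gsdmc2, a gasdermin family gene, fell by 2.96 ± 0.38 and Pnliprp2, a lipase-related gene, fell by 2.71 ± 0.35. Bhlha15 differed by -0.35 ± 0.26, Cd24a by 0.04 ± 0.18, Atoh1 by 0.08 ± 0.20, Lyz1 by -0.30 ± 0.28, Muc2 by -0.24 ± 0.26 and Chga by -0.22 ± 0.65, short of the threshold. Dclk1 differed by -0.99 ± 0.45, Olfm4 by -1.20 ± 0.31, Mki67 by -0.23 ± 0.31, Cdkn1a by -0.57 ± 0.29 and Hes1 by -0.42 ± 0.34, also short of it. In all, 28 genes passed, 11 higher and 17 lower. The MHC class II list test gave adjusted p = 5.07e-14, and adjusted p = 0.0141 with an estimated correlation, which became 0.0514 without untreated CD24lo replicate 1 and 0.113 without Lgr5-ablated CD24lo replicate 2. The Paneth list gave 0.000136 and adjusted p = 0.162 with an estimated correlation. The T cell list also passed, with a median of 0.59 and adjusted p = 0.0372, which became 0.676 without untreated CD24lo replicate 1 and 0.223 without Lgr5-ablated CD24lo replicate 2, and adjusted p = 0.779 with an estimated correlation. The B and plasma cell list passed downward, with a median of -0.73 and adjusted p = 0.015, which became 0.4 without untreated CD24lo replicate 2 and 0.646 without Lgr5-ablated CD24lo replicate 2, and adjusted p = 0.796 with an estimated correlation. The pan-epithelial list passed downward, with a median of -0.26 and adjusted p = 0.015, which became 0.098 without untreated CD24lo replicate 2 and 0.0673 without Lgr5-ablated CD24lo replicate 2, and adjusted p = 0.562 with an estimated correlation. Leaving out 1 array, limma called 12 genes without untreated CD24lo replicate 1 (1 MHC class II and 1 Paneth genes) and 17 without untreated CD24lo replicate 2 (4 MHC class II genes). It called 46 without Lgr5-ablated CD24lo replicate 1 and 23 without Lgr5-ablated CD24lo replicate 2 (1 MHC class II and 1 Paneth genes). A fit to the 4 arrays compared alone called 0 genes, with 485 at an unadjusted p below 0.05.

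In CD24hi cells after Lgr5 ablation, the largest rises included genes that interferon induces. Cxcl9 rose by 5.26 ± 0.47, adjusted p = 1.76e-05, Ido1 by 4.52 ± 0.43, the related chemokine gene Cxcl10 by 3.93 ± 0.61, and Gbp2, a guanylate-binding protein of cell defence, by 3.82 ± 0.43. Over the interferon list 3 of 21 members rose (7 adjusted over the list alone; median 0.66). MHC class II genes rose in 4 of 6 members (6 adjusted over the list alone; median 1.31), with Cd74, the chaperone of MHC class II, at 1.68 ± 0.30. The goblet cell gene Clca1 rose by 1.40 ± 0.18, and the Paneth list gene Copz2 fell by 1.89 ± 0.25. Of the regeneration and YAP list, genes raised in repairing epithelium, only 4 of 13 genes were tested. Of these 4, 2 rose (2 adjusted over the list alone). They were Il1rn, an antagonist of interleukin 1, at 4.35 ± 0.75 and Clu (clusterin) at 3.57 ± 0.71. Lgr5 measured 11.48 and 10.95 in untreated and 10.17 and 9.65 in ablated arrays (-1.30 ± 0.56, adjusted p = 0.455), and the stem cell gene Olfm4 differed by -1.31 ± 0.31, adjusted p = 0.0536, neither past the threshold. Bhlha15 differed by -0.42 ± 0.26, Cd24a by -0.31 ± 0.18, Atoh1 by 0.34 ± 0.20, Lyz1 by -0.20 ± 0.28 and Muc2 by 0.00 ± 0.26, short of the threshold. Chga differed by 1.46 ± 0.65, Dclk1 by 0.60 ± 0.45, Mki67 by 0.07 ± 0.31, Cdkn1a by 0.96 ± 0.29 and Hes1 by 0.05 ± 0.34, also short of it. In all, 101 genes passed, 68 higher and 33 lower. By camera the lists gave adjusted p = 1.1e-08 for interferon, 2.11e-10 for MHC class II and 0.0106 for regeneration genes. With an estimated correlation they gave adjusted p = 0.186, 0.0408 and 0.144, the second becoming 0.0625 without untreated CD24hi replicate 1, 0.0991 without untreated CD24hi replicate 2, 0.0958 without Lgr5-ablated CD24hi replicate 1 and 0.0907 without Lgr5-ablated CD24hi replicate 2. The T cell list also passed, with a median of 0.61 and adjusted p = 0.0125, which became 0.914 without untreated CD24hi replicate 2 and 0.532 without Lgr5-ablated CD24hi replicate 2, and adjusted p = 0.384 with an estimated correlation. With 1 array left out, limma called 55 genes without untreated CD24hi replicate 1 (1 MHC class II gene, and 0 regeneration genes against 3 at an unadjusted p below 0.05). It called 36 without untreated CD24hi replicate 2 (0 MHC class II and 0 regeneration genes against 5 and 2 at an unadjusted p below 0.05). It called 55 without Lgr5-ablated CD24hi replicate 1 (1 MHC class II gene, and 0 regeneration genes against 2 at an unadjusted p below 0.05). It called 186 without Lgr5-ablated CD24hi replicate 2 (2 MHC class II genes). The regeneration list gave adjusted p = 0.0527 without Lgr5-ablated CD24hi replicate 2. Calls were lost without untreated CD24hi replicate 1 for Cd74 (0.0965), Il1rn (0.0551) and Clu (0.134) and without untreated CD24hi replicate 2 for Cd74 (0.0678), Il1rn (0.0729) and Clu (0.12). Further losses came without Lgr5-ablated CD24hi replicate 1 for Cd74 (0.116), Il1rn (0.0683) and Clu (0.238), adjusted p in parentheses.

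The effect of ablation differed between the fractions for 2 genes, with a more positive effect in CD24hi cells for AW112010, by 2.78 ± 0.24, adjusted p = 1.89e-05, and for Clca1, by 1.60 ± 0.25, adjusted p = 0.0471. Only the first kept its call without any 1 array, since Clca1 gave 0.0956 without untreated CD24lo replicate 1, 0.363 without untreated CD24lo replicate 2, 0.144 without untreated CD24hi replicate 1, 0.157 without untreated CD24hi replicate 2, 0.194 without Lgr5-ablated CD24lo replicate 1, 0.13 without Lgr5-ablated CD24lo replicate 2 and 0.338 without Lgr5-ablated CD24hi replicate 1. In this test between fractions, Bhlha15 differed by -0.06 ± 0.37, Cd24a by -0.35 ± 0.25, Lgr5 by 0.11 ± 0.80, Atoh1 by 0.27 ± 0.29, Lyz1 by 0.10 ± 0.40 and Muc2 by 0.25 ± 0.37, short of the threshold. Chga differed by 1.68 ± 0.92, Dclk1 by 1.59 ± 0.63, Olfm4 by -0.12 ± 0.43, Mki67 by 0.30 ± 0.44, Cdkn1a by 1.53 ± 0.41 and Hes1 by 0.47 ± 0.48, also short of it.

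Irradiation asked how the Mist1-positive cells respond to DNA damage. In CD24lo cells, targets of p53, the transcription factor of the DNA damage response, rose in 13 of 23 members (18 adjusted over the list alone; median 1.29). Phlda3, which restrains Akt signalling, rose by 4.75 ± 0.44, adjusted p = 1.69e-05, the receptor gene Eda2r by 4.59 ± 0.62, and the kinase gene Plk2 by 2.64 ± 0.35. Genes of the G2 and M phases of the cell cycle fell in 16 of 19 members (18 adjusted over the list alone; median -1.36), with Birc5 (survivin) at -1.93 ± 0.32. S phase genes fell in 4 of 20 (9 adjusted over the list alone; median -0.81). Stem cell genes fell in 6 of 16 members (7 adjusted over the list alone; median -0.71), Olfm4 most, at -3.71 ± 0.31, adjusted p = 4.08e-06, then Lgr5 at -2.35 ± 0.56. MHC class II genes fell in 5 of 6 members (5 adjusted over the list alone; median -1.74), with H2-DMa at -2.20 ± 0.26 and Cd74 at -2.19 ± 0.30. Among the largest changes, Gsdmc2 fell by 6.23 ± 0.38, to a level below the middle of the arrays, while Mbl2, a mannose-binding lectin, rose by 4.88 ± 0.46 and the epoxide hydrolase gene Ephx1 by 4.27 ± 0.35. Atoh1, the transcription factor of the secretory lineage, differed by 0.73 ± 0.20, adjusted p = 0.0526, short of the threshold. Mki67 was lower, at -1.68 ± 0.31, adjusted p = 0.00584, which became 0.0782 without irradiated CD24lo replicate 2. Cdkn1a was higher by 1.43 ± 0.29, adjusted p = 0.00963, which became 0.0679 without untreated CD24lo replicate 1 and 0.151 without irradiated CD24lo replicate 1. Bhlha15 differed by -0.04 ± 0.26, Cd24a by 0.35 ± 0.18, Lyz1 by -0.10 ± 0.28 and Muc2 by -0.01 ± 0.26, short of the threshold. Chga differed by 0.15 ± 0.65, Dclk1 by -0.15 ± 0.45 and Hes1 by 0.17 ± 0.34, also short of it. Of 477 genes past the threshold, 187 were higher and 290 lower. The p53 list gave adjusted p = 4.74e-20, and adjusted p = 0.00242 with an estimated correlation. The G2/M list gave 1.49e-16, the S phase list 9.14e-07, the stem cell list 0.000115 and the MHC class II list 3.79e-07, and with an estimated correlation these gave adjusted p = 0.136, 0.44, 0.502 and 0.0821. Leave-one-out fits with limma called 322 genes without untreated CD24lo replicate 1 (2 stem cell genes). It called 147 without untreated CD24lo replicate 2 (6 G2/M, 2 stem cell and 3 MHC class II genes, and 0 S phase genes against 5 at an unadjusted p below 0.05). It called 112 without irradiated CD24lo replicate 1 (10 G2/M and 3 stem cell genes, and 0 S phase genes against 11 at an unadjusted p below 0.05). It called 195 without irradiated CD24lo replicate 2 (5 G2/M and 2 S phase genes). Lgr5 gave adjusted p = 0.109 without untreated CD24lo replicate 1, 0.0924 without untreated CD24lo replicate 2 and 0.339 without irradiated CD24lo replicate 1.

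Irradiated CD24hi cells showed p53 targets higher in 10 of 23 members (17 adjusted over the list alone; median 1.08), with Phlda3 at 4.10 ± 0.44, adjusted p = 4.41e-05, and Cdkn1a, the cell cycle inhibitor p21, at 2.09 ± 0.29. G2/M genes fell in 17 of 19 members, also adjusted over the list alone (median -1.65), with the topoisomerase gene Top2a at -2.13 ± 0.27 and the proliferation marker Mki67 at -2.06 ± 0.31. S phase genes fell in 13 of 20 (17 adjusted over the list alone; median -1.25). Stem cell genes fell in 5 of 16, also adjusted over the list alone (median -0.49), with Olfm4 at -3.20 ± 0.31 and the water channel gene Aqp4 at -2.88 ± 0.27. Lgr5 differed by -0.47 ± 0.56, adjusted p = 0.758. MHC class II genes fell in 5 of 6, also adjusted over the list alone (median -2.69), with H2-Aa at -2.91 ± 0.33 and H2-DMa at -2.77 ± 0.26. Interferon genes fell in 5 of 21 (7 adjusted over the list alone), the immunoproteasome gene Psmb9 most, at -2.03 ± 0.20. Goblet cell genes rose in 6 of 20, also adjusted over the list alone (median 0.40), with Clca1 at 1.61 ± 0.18 and Bcas1 at 1.48 ± 0.20. Genes of pancreatic acinar cells rose in 5 of 7 members (7 adjusted over the list alone; median 2.82), and Cel, a lipase of that cell type, measured 9.02 and 7.29 in the irradiated against 4.55 and 4.81 in the untreated arrays. B and plasma cell genes fell in 2 of 11 members (3 adjusted over the list alone). Bhlha15 differed by 0.50 ± 0.26, Cd24a by -0.04 ± 0.18, Atoh1 by 0.60 ± 0.20 and Lyz1 by -0.28 ± 0.28, short of the threshold. Muc2 differed by 0.08 ± 0.26, Chga by -0.48 ± 0.65, Dclk1 by -0.60 ± 0.45 and Hes1 by 0.06 ± 0.34, also short of it. In all, 526 genes passed, 131 higher and 395 lower. With the preset correlation the list tests gave adjusted p = 1.54e-18 for p53, 1.83e-22 for G2/M, 1.06e-16 for S phase, 6.92e-07 for stem cell, 6.04e-12 for MHC class II, 1.01e-06 for interferon, 1.52e-07 for goblet, 4.7e-10 for acinar and 0.0047 for B and plasma cell genes. In that order they gave adjusted p = 0.00357, 0.0504, 0.0504, 0.209, 0.0151, 0.218, 0.285, 0.0557 and 0.514 with an estimated correlation. Leaving out 1 array, limma called 242 genes without untreated CD24hi replicate 1 (6 S phase, 3 stem cell, 3 goblet, 3 acinar, 2 interferon and 1 B and plasma cell genes). It called 323 without untreated CD24hi replicate 2 (6 S phase, 2 acinar and 2 interferon genes, and 0 B and plasma cell genes against 4 at an unadjusted p below 0.05). It called 163 without irradiated CD24hi replicate 1 (3 S phase, 9 G2/M, 3 stem cell, 2 interferon and 1 B and plasma cell genes, and 0 acinar genes against 5 at an unadjusted p below 0.05). It called 530 without irradiated CD24hi replicate 2 (2 interferon genes, and 0 B and plasma cell genes against 3 at an unadjusted p below 0.05). The B and plasma cell list gave adjusted p = 0.0639 without irradiated CD24hi replicate 2. The test of the difference between fractions passed for 1 gene, Clca1, whose effect was more positive in CD24hi cells by 1.72 ± 0.25, adjusted p = 0.0393. Its adjusted p became 0.0888 without untreated CD24lo replicate 1, 0.49 without untreated CD24lo replicate 2, 0.218 without untreated CD24hi replicate 1, 0.287 without untreated CD24hi replicate 2, 0.089 without irradiated CD24lo replicate 1, 0.145 without irradiated CD24lo replicate 2 and 0.0804 without irradiated CD24hi replicate 2. In this test between fractions, Bhlha15 differed by 0.54 ± 0.37, Cd24a by -0.39 ± 0.25, Lgr5 by 1.88 ± 0.80, Atoh1 by -0.13 ± 0.29, Lyz1 by -0.18 ± 0.40 and Muc2 by 0.09 ± 0.37, short of the threshold. Chga differed by -0.62 ± 0.92, Dclk1 by -0.45 ± 0.63, Olfm4 by 0.51 ± 0.43, Mki67 by -0.38 ± 0.44, Cdkn1a by 0.66 ± 0.41 and Hes1 by -0.10 ± 0.48, also short of it.

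**Figure D2:**
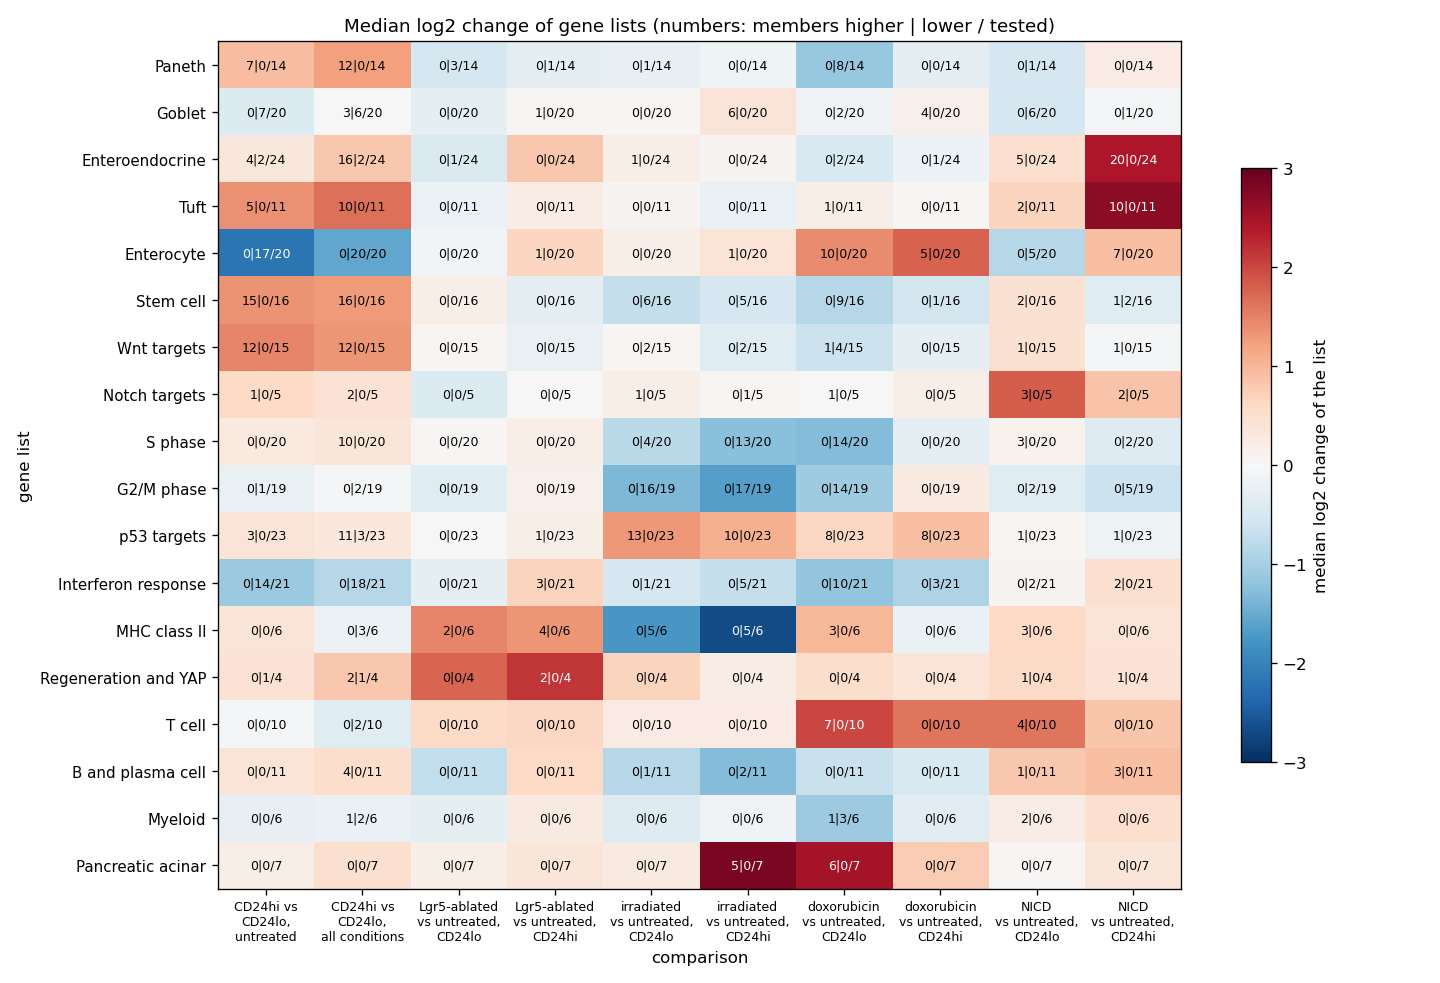
Median log2 difference of 18 gene lists (vertical) in the 10 comparisons (horizontal), from -3 in blue to 3 in red, with the members higher and lower past the threshold over the members tested written in each cell. The G2/M list stood at -1.36 in irradiated CD24lo and -1.65 in irradiated CD24hi cells, and the tuft list at 2.68 in CD24hi cells with NICD.

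Doxorubicin asked the same question with a drug. In CD24lo cells, S phase genes fell in 14 of 20 members (15 adjusted over the list alone; median -1.30), with Mcm5, a subunit of the replication helicase, at -2.11 ± 0.33, adjusted p = 0.00121. G2/M genes fell in 14 of 19 (17 adjusted over the list alone; median -1.07). Stem cell genes fell in 9 of 16 (11 adjusted over the list alone; median -0.86), Olfm4 at -3.18 ± 0.31, Lgr5 at -3.11 ± 0.56 and Smoc2 at -2.31 ± 0.22. Paneth genes fell in 8 of 14 (9 adjusted over the list alone; median -1.13), with the antimicrobial phospholipase gene Pla2g2a at -2.70 ± 0.42 and Mptx1, a pentraxin, at -2.63 ± 0.50. Enterocyte genes rose in 10 of 20 (16 adjusted over the list alone; median 1.41), and p53 targets in 8 of 23 (10 adjusted over the list alone; median 0.63). Cubn (cubilin), an endocytic receptor, rose by 4.66 ± 0.42, and Gsdmc2 fell by 5.91 ± 0.38. Bhlha15 fell by 1.19 ± 0.26, with adjusted p = 0.00829, which became 0.0615 without untreated CD24lo replicate 2 and 0.079 without doxorubicin CD24lo replicate 2. Other probe sets fell short of the threshold here, at -0.47 for Bhlha15, adjusted p = 0.39, and at -0.85 for Lgr5, adjusted p = 0.131. The list tests gave adjusted p = 2.86e-09 for S phase, 2.86e-09 for G2/M, 3.35e-06 for stem cell, 7.25e-06 for Paneth, 1.35e-08 for enterocyte and 2.21e-07 for p53 genes. In that order they gave adjusted p = 0.144, 0.177, 0.177, 0.144, 0.239 and 0.125 with an estimated correlation. With 1 array left out, limma called 1440 genes without untreated CD24lo replicate 1 (5 stem cell genes). It called 399 without untreated CD24lo replicate 2 (5 S phase, 5 G2/M, 4 stem cell and 1 enterocyte genes). It called 394 without doxorubicin CD24lo replicate 1 (9 S phase, 6 G2/M, 3 stem cell, 1 enterocyte and 5 p53 genes). It called 543 without doxorubicin CD24lo replicate 2 (6 S phase, 5 G2/M, 3 stem cell, 1 enterocyte and 5 p53 genes), against 1747 with every array.

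Genes of other cell types also moved in CD24lo cells after doxorubicin. T cell genes rose in 7 of 10 members (10 adjusted over the list alone; median 2.01), and Gzma, a granzyme of cytotoxic lymphocytes, measured 10.36 and 10.39 in the treated arrays, a difference of 3.48 ± 0.68, adjusted p = 0.00431. Acinar genes rose in 6 of 7 (7 adjusted over the list alone; median 2.49), and the elastase gene Cela2a rose by 3.30 ± 0.66, with adjusted p = 0.00483, which became 0.0734 without doxorubicin CD24lo replicate 1. Of the myeloid list 1 rose and 3 fell of 6 (1 and 4 adjusted over the list alone; median -1.09), with Cd14, a receptor for bacterial lipopolysaccharide, at -2.43 ± 0.33. MHC class II genes rose in 3 of 6 (5 adjusted over the list alone; median 0.99), with H2-Aa at 2.00 ± 0.33. Interferon genes fell in 10 of 21 (15 adjusted over the list alone; median -1.18). The Reg family, secreted lectins of gut defence, went both ways, 2 higher and 1 lower of 5 (the same adjusted over the list alone), with Reg1 at 2.70 ± 0.74 and Reg3g at -2.58 ± 0.28. So did the unfolded protein response, 2 higher and 3 lower of 21 (the same adjusted over the list alone), with the asparagine synthetase gene Asns at -1.14 ± 0.18. Mki67 was lower, at -0.98 ± 0.31, adjusted p = 0.0427, which became 0.0994 without untreated CD24lo replicate 1, 0.171 without untreated CD24lo replicate 2, 0.262 without doxorubicin CD24lo replicate 1 and 0.0825 without doxorubicin CD24lo replicate 2. Cd24a differed by -0.06 ± 0.18, Atoh1 by 0.23 ± 0.20, Lyz1 by -0.32 ± 0.28 and Muc2 by 0.08 ± 0.26, short of the threshold. Chga differed by -0.30 ± 0.65, Dclk1 by 0.04 ± 0.45, Cdkn1a by 0.24 ± 0.29 and Hes1 by -0.02 ± 0.34, also short of it. Of 1747 genes past the threshold, 648 were higher and 1099 lower. Tested as lists, these gave adjusted p = 1.01e-07 for T cell, 1.19e-06 for acinar, 0.0337 for myeloid, 0.000115 for MHC class II, 1.19e-06 for interferon, 0.892 for Reg and 0.459 for unfolded protein genes, the last 2 not past the threshold. The others gave adjusted p = 0.144, 0.144, 0.29, 0.144 and 0.177 with an estimated correlation, and the myeloid list gave 0.172 without untreated CD24lo replicate 2 and 0.0758 without doxorubicin CD24lo replicate 2. Reg1 gave adjusted p = 0.198 without untreated CD24lo replicate 2, 0.109 without doxorubicin CD24lo replicate 1 and 0.109 without doxorubicin CD24lo replicate 2. Leave-one-out fits with limma called 1440 genes without untreated CD24lo replicate 1 (4 T cell, 2 acinar and 5 interferon genes). It called 399 without untreated CD24lo replicate 2 (2 acinar, 6 interferon, 1 Reg and 1 unfolded protein genes). It called 394 without doxorubicin CD24lo replicate 1 (3 T cell, 4 interferon, 2 myeloid, 1 Reg and 1 unfolded protein genes, and 0 acinar genes against 4 at an unadjusted p below 0.05). It called 543 without doxorubicin CD24lo replicate 2 (2 T cell, 4 interferon, 1 myeloid, 1 Reg and 2 unfolded protein genes).

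CD24hi cells after doxorubicin had p53 targets higher in 8 of 23 members (15 adjusted over the list alone; median 0.90), with Phlda3 at 3.37 ± 0.44, adjusted p = 0.000697. Goblet genes rose in 4 of 20 (5 adjusted over the list alone; median 0.16), Clca1 most, by 1.91 ± 0.18. Enterocyte genes rose in 5 of 20 (16 adjusted over the list alone; median 1.78), with Lct at 2.82 ± 0.48. Cyp3a11, a cytochrome P450 of drug metabolism, rose by 3.70 ± 0.45 and the carboxylesterase gene Ces1g by 3.64 ± 0.40, while Gsdmc2 fell by 3.13 ± 0.38. The T cell list had a median of 1.62, and the proliferation marker Mki67 differed by 0.30 ± 0.31, adjusted p = 0.777. Bhlha15 differed by -0.41 ± 0.26, Cd24a by -0.09 ± 0.18, Lgr5 by -1.40 ± 0.56, Atoh1 by 0.31 ± 0.20, Lyz1 by -0.89 ± 0.28 and Muc2 by 0.10 ± 0.26, short of the threshold. Chga differed by -0.38 ± 0.65, Dclk1 by 0.02 ± 0.45, Olfm4 by -0.77 ± 0.31, Cdkn1a by 1.07 ± 0.29 and Hes1 by 0.14 ± 0.34, also short of it. The other Cdkn1a probe set passed, at 1.12, adjusted p = 0.038. Of 142 genes past the threshold, 95 were higher and 47 lower. By camera the lists gave adjusted p = 1.05e-14 for p53, 0.00971 for goblet, 5.94e-14 for enterocyte and 1.1e-07 for T cell genes, and in that order adjusted p = 0.00833, 0.623, 0.237 and 0.158 with an estimated correlation. Leaving out 1 array, limma called 82 genes without untreated CD24hi replicate 1. It called 29 without untreated CD24hi replicate 2 (2 p53 and 2 goblet genes, and 0 enterocyte genes against 13 at an unadjusted p below 0.05). It called 26 without doxorubicin CD24hi replicate 1 (2 p53 and 2 goblet genes, and 0 enterocyte genes against 16 at an unadjusted p below 0.05). It called 26 without doxorubicin CD24hi replicate 2 (3 p53 and 1 goblet genes, and 0 enterocyte genes against 15 at an unadjusted p below 0.05). The goblet list gave adjusted p = 0.635 without untreated CD24hi replicate 1, and Lct gave 0.0787 without untreated CD24hi replicate 2, 0.0699 without doxorubicin CD24hi replicate 1 and 0.116 without doxorubicin CD24hi replicate 2. The pancreatic acinar list passed too, with a median of 0.76 and adjusted p = 0.0251, which became 0.0911 without untreated CD24hi replicate 2, and adjusted p = 0.623 with an estimated correlation. The B and plasma cell list passed downward too, with a median of -0.46 and adjusted p = 0.0392, which became 0.127 without untreated CD24hi replicate 2, 0.0584 without doxorubicin CD24hi replicate 1 and 0.0534 without doxorubicin CD24hi replicate 2, and adjusted p = 0.623 with an estimated correlation.

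The effect of doxorubicin differed between the fractions for 4 genes, each with a more positive effect in CD24hi cells. The Paneth list gene Mmp7, a metalloprotease that activates defensins, differed by 2.32 ± 0.36, adjusted p = 0.0337, the defensin gene Defa39 by 2.24 ± 0.38, Stil, a centriole assembly gene, by 2.13 ± 0.34 and Clca1 by 1.89 ± 0.25. Mmp7 fell by 2.39 ± 0.25 in CD24lo cells. Calls were lost without untreated CD24lo replicate 2 for Mmp7 (0.132), Defa39 (0.132), Stil (0.132) and Clca1 (0.132) and without untreated CD24hi replicate 1 for Mmp7 (0.172), Defa39 (0.172), Stil (0.172) and Clca1 (0.0769). Further losses came without doxorubicin CD24lo replicate 1 for Mmp7 (0.154), Defa39 (0.189), Stil (0.154) and Clca1 (0.104) and without doxorubicin CD24lo replicate 2 for Mmp7 (0.111), Defa39 (0.147), Stil (0.141) and Clca1 (0.0531). They were also lost without doxorubicin CD24hi replicate 1 for Mmp7 (0.267), Defa39 (0.267), Stil (0.267) and Clca1 (0.177) and without doxorubicin CD24hi replicate 2 for Mmp7 (0.149), Defa39 (0.302), Stil (0.201) and Clca1 (0.063). Further losses came without untreated CD24lo replicate 1 for Defa39 (0.0802) and Stil (0.0608) and without untreated CD24hi replicate 2 for Defa39 (0.122), adjusted p in parentheses. Olfm4, which fell in CD24lo cells, had a difference between fractions of 2.41 ± 0.43, adjusted p = 0.0516, just short of the threshold. In this test between fractions, Bhlha15 differed by 0.78 ± 0.37, Cd24a by -0.03 ± 0.25, Lgr5 by 1.71 ± 0.80, Atoh1 by 0.08 ± 0.29, Lyz1 by -0.57 ± 0.40 and Muc2 by 0.01 ± 0.37, short of the threshold. Chga differed by -0.08 ± 0.92, Dclk1 by -0.03 ± 0.63, Mki67 by 1.29 ± 0.44, Cdkn1a by 0.83 ± 0.41 and Hes1 by 0.16 ± 0.48, also short of it.

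**Figure D3:**
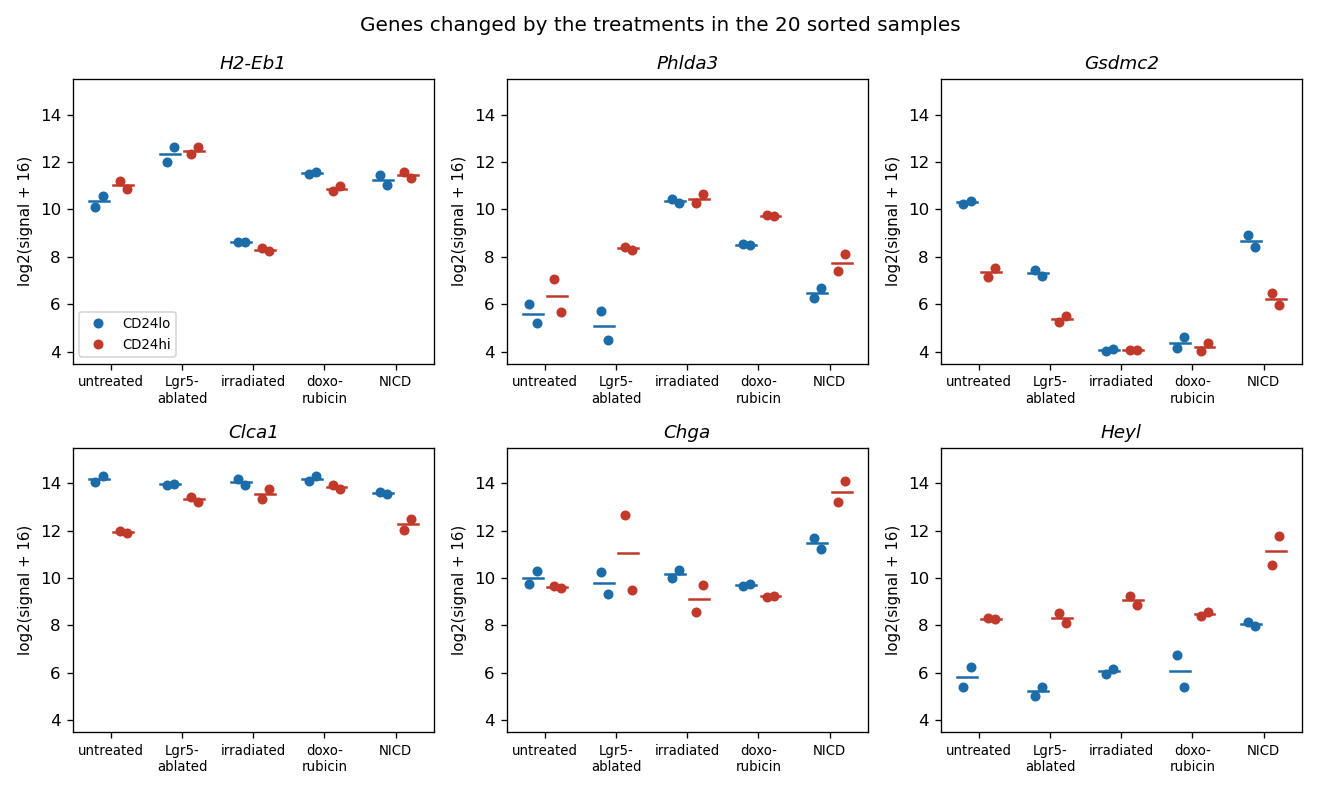
Signal of H2-Eb1, Phlda3, Gsdmc2, Clca1, Chga and Heyl in each sorted array, as log2(signal + 16) on the vertical axis against the 5 conditions for CD24lo and CD24hi cells, with each point an array and each bar the mean of 2. Mean Phlda3 was 5.61 ± 0.58 (SD) in untreated and 10.36 ± 0.10 in irradiated CD24lo cells, and mean Gsdmc2 was 10.30 ± 0.09 and 4.07 ± 0.04 in the same groups.

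The NICD condition asked what Notch signalling does in these cells, as far as its name tells. Replicate 2 of the CD24hi group is the array that stood apart in control probes, and a fit without replicate 1 has no other array of this group. In CD24hi cells with NICD, tuft cell genes rose in 10 of 11 members (11 adjusted over the list alone; median 2.68), with Siglecf, a sialic acid receptor, at 3.70 ± 0.51, adjusted p = 0.000461, and Dclk1 at 3.01 ± 0.45, where another probe set of Dclk1 gave 1.87, adjusted p = 0.0645. Enteroendocrine genes rose in 20 of 24 (21 adjusted over the list alone; median 2.42), with Tph1, an enzyme of serotonin synthesis, at 4.07 ± 0.65 and Chga (chromogranin A) at 4.02 ± 0.65. Notch targets rose in 2 of 5 (4 adjusted over the list alone; median 0.87), Heyl, a transcription factor induced by Notch, at 2.87 ± 0.43 and the receptor gene Notch3 at 1.63 ± 0.37. Notch1 differed by -0.63 ± 0.30, adjusted p = 0.218, but the files do not tell whether its probe set detects a transgene, here or in CD24lo cells. Of Notch ligands and secretory regulators 2 rose and 1 fell of 14 (2 and 3 adjusted over the list alone), the lower one Atoh1, which Notch signalling represses, at -0.76 ± 0.20. G2/M genes fell in 5 of 19 (10 adjusted over the list alone; median -0.65). The largest rises were Gkn1, a gastrokine of the stomach lining, by 7.07 ± 0.65 and Afp (alpha-fetoprotein) by 6.99 ± 1.30. The largest fall to keep its call without any 1 array was that of Erdr1, which fell by 3.62 ± 0.63. Of the stromal list only 3 of 15 genes were tested, and 1 rose (2 adjusted over the list alone), the intermediate filament gene Vim at 3.01 ± 0.47. B and plasma cell genes rose in 3 of 11 (5 adjusted over the list alone). The T cell list passed too, with a median of 0.82 and adjusted p = 0.0401, which became 0.768 without untreated CD24hi replicate 2 and 0.167 without NICD CD24hi replicate 1, and adjusted p = 0.493 with an estimated correlation. Cdkn1a was higher by 1.64 ± 0.29, adjusted p = 0.00239, which became 0.0516 without NICD CD24hi replicate 2. Bhlha15 differed by -0.84 ± 0.26, Cd24a by 0.22 ± 0.18, Lgr5 by 0.81 ± 0.56 and Lyz1 by 0.39 ± 0.28, short of the threshold. Muc2 differed by 0.35 ± 0.26, Olfm4 by -0.89 ± 0.31, Mki67 by -0.80 ± 0.31 and Hes1 by 0.87 ± 0.34, also short of it. In all, 778 genes passed, 557 higher and 221 lower. The tuft list gave adjusted p = 4.41e-14, and adjusted p = 0.0141 with an estimated correlation, which became 0.133 without NICD CD24hi replicate 1. The list tests gave 1.25e-18 for enteroendocrine, 0.00255 for Notch target, 4e-07 for G2/M, 0.0194 for stromal and 0.00256 for B and plasma cell genes, and with an estimated correlation adjusted p = 0.143, 0.103, 0.399, 0.316 and 0.493. The stromal list gave 0.0624 without NICD CD24hi replicate 1, and the B and plasma cell list 0.0624 without NICD CD24hi replicate 1. Notch ligands and secretory regulators, with a median of 0.00 and a test direction of lower, did not pass (0.937). With 1 array left out, limma called 378 genes without untreated CD24hi replicate 1 (0 G2/M, 0 Notch ligand and secretory and 0 B and plasma cell genes against 6, 5 and 4 at an unadjusted p below 0.05). It called 248 without untreated CD24hi replicate 2 (12 enteroendocrine, 1 Notch target and 1 G2/M genes, and 0 Notch ligand and secretory and 0 B and plasma cell genes against 5 and 4 at an unadjusted p below 0.05). It called 2238 without NICD CD24hi replicate 1 (5 Notch ligand and secretory genes). It called 206 without NICD CD24hi replicate 2 (13 enteroendocrine and 1 Notch target genes, and 0 G2/M, 0 Notch ligand and secretory and 0 B and plasma cell genes against 13, 4 and 4 at an unadjusted p below 0.05). Calls of Notch3 and Atoh1 were lost without replicate 2 of untreated or NICD CD24hi cells. That of Atoh1 was also lost without untreated CD24hi replicate 1.

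In CD24lo cells with NICD, Notch targets rose in 3 of 5 members, also adjusted over the list alone (median 1.83), with Heyl at 2.25 ± 0.43, adjusted p = 0.00959, Notch3 at 2.10 ± 0.37 and Nrarp, a feedback inhibitor of Notch, at 1.83 ± 0.29. Goblet genes fell in 6 of 20 (9 adjusted over the list alone; median -0.53), and enterocyte genes in 5 of 20 (7 adjusted over the list alone; median -0.86). Enteroendocrine genes rose in 5 of 24 (6 adjusted over the list alone; median 0.50), Tph1 most, by 2.52 ± 0.65. T cell list genes rose in 4 of 10 (6 adjusted over the list alone; median 1.61), with the leukocyte gene Ptprc (CD45) at 4.41 ± 0.70. Gkn1 rose by 5.54 ± 0.65 and Erdr1 fell by 5.27 ± 0.63, and of the 53 named genes past the threshold these were the 2 that kept their call without any 1 array. The 18S control signal was 15116 and 12120 on the CD24lo NICD arrays, against 48619 on CD24hi NICD replicate 2, which stood apart, and 18227 to 29228 on 17 others. Bhlha15 differed by -0.30 ± 0.26, Cd24a by 0.05 ± 0.18, Lgr5 by 1.46 ± 0.56, Atoh1 by 0.25 ± 0.20, Lyz1 by -0.58 ± 0.28, Muc2 by -0.41 ± 0.26 and Chga by 1.45 ± 0.65, short of the threshold. The other Bhlha15 probe set passed, at -1.12, adjusted p = 0.0447. Dclk1 differed by 0.55 ± 0.45, Olfm4 by 0.42 ± 0.31, Mki67 by -0.27 ± 0.31, Cdkn1a by -0.48 ± 0.29, Hes1 by 0.10 ± 0.34 and Notch1 by 0.19 ± 0.30, also short of it. Of 1709 genes past the threshold, 794 were higher and 915 lower. Tested as lists, these gave adjusted p = 0.0287 for Notch target, 0.00189 for goblet, 0.000177 for enterocyte, 0.0287 for enteroendocrine and 0.00674 for T cell genes, each against adjusted p = 0.569 with an estimated correlation, or 0.657 for the enteroendocrine list. The Notch target list gave 0.0817 without NICD CD24lo replicate 1, and the enteroendocrine list 0.153 without untreated CD24lo replicate 1 and 0.0867 without NICD CD24lo replicate 1. Leave-one-out fits with limma called 383 genes without untreated CD24lo replicate 1 (2 goblet, 3 enterocyte, 1 enteroendocrine and 2 T cell genes). It called 581 without untreated CD24lo replicate 2 (2 enterocyte and 3 enteroendocrine genes, and 0 goblet genes against 3 at an unadjusted p below 0.05). It called 1741 without NICD CD24lo replicate 1 (3 goblet, 3 enteroendocrine and 1 T cell genes). It called 4 without NICD CD24lo replicate 2 (0 Notch target, 0 goblet, 0 enterocyte, 0 enteroendocrine and 0 T cell genes against 3, 5, 6, 8 and 5 at an unadjusted p below 0.05). Calls were lost without untreated CD24lo replicate 1 for Heyl (0.0543) and Tph1 (0.115) and without NICD CD24lo replicate 2 for Heyl (0.138), Notch3 (0.138), Nrarp (0.138), Tph1 (0.235) and Ptprc (0.133). Further losses came without NICD CD24lo replicate 1 for Tph1 (0.0552), adjusted p in parentheses.

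The effect of NICD differed between the fractions for 314 genes, 194 with a more positive and 120 with a more negative effect in CD24hi cells. Enterocyte genes were among the former, with the apolipoprotein gene Apoa4 at 4.05 ± 0.66, adjusted p = 0.0122, and Lct at 3.75 ± 0.68. The tuft cell gene Trpm5, an ion channel, was too, at 3.12 ± 0.71. The S phase gene Mcm4 was among the latter, at -1.58 ± 0.37, while Chga, at 2.57 ± 0.92, adjusted p = 0.0992, did not pass. The effect on Dclk1 was more positive in CD24hi cells by 2.46 ± 0.63, adjusted p = 0.0488, which became 0.0721 without untreated CD24lo replicate 1, 0.117 without untreated CD24lo replicate 2, 0.0618 without untreated CD24hi replicate 1, 0.111 without untreated CD24hi replicate 2, 0.0739 without NICD CD24lo replicate 1, 0.183 without NICD CD24lo replicate 2 and 0.237 without NICD CD24hi replicate 2. Another probe set of Dclk1 passed at 2.54, adjusted p = 0.0457, and the remaining ones fell short at 0.70 to 1.49, with adjusted p from 0.109 to 0.618. The effect on Cdkn1a was more positive in CD24hi cells by 2.12 ± 0.41, adjusted p = 0.0298, which became 0.0836 without untreated CD24lo replicate 2, 0.0633 without untreated CD24hi replicate 1, 0.0685 without untreated CD24hi replicate 2, 0.179 without NICD CD24lo replicate 2 and 0.15 without NICD CD24hi replicate 2. In this test between fractions, Bhlha15 differed by -0.54 ± 0.37, Cd24a by 0.17 ± 0.25, Lgr5 by -0.65 ± 0.80, Atoh1 by -1.01 ± 0.29 and Lyz1 by 0.98 ± 0.40, short of the threshold. Muc2 differed by 0.76 ± 0.37, Olfm4 by -1.31 ± 0.43, Mki67 by -0.52 ± 0.44, Hes1 by 0.77 ± 0.48 and Notch1 by -0.82 ± 0.43, also short of it. The total was 38 without untreated CD24lo replicate 1, 27 without untreated CD24lo replicate 2, 10 without untreated CD24hi replicate 1, 21 without untreated CD24hi replicate 2, 753 without NICD CD24lo replicate 1, 0 without NICD CD24lo replicate 2, 2622 without NICD CD24hi replicate 1 and 5 without NICD CD24hi replicate 2, with 1850 genes at an unadjusted p below 0.05 in limma where it was 0. Each of the 24 named genes lost its call without at least 1 array, here without untreated CD24hi replicate 1 for Apoa4 (0.0609), Lct (0.0618), Trpm5 (0.0982) and Mcm4 (0.135) and without NICD CD24lo replicate 2 for Apoa4 (0.113), Lct (0.148), Trpm5 (0.215) and Mcm4 (0.199). Further losses came without NICD CD24hi replicate 2 for Apoa4 (0.087), Lct (0.15), Trpm5 (0.206) and Mcm4 (0.211) and without untreated CD24lo replicate 2 for Lct (0.0573), Trpm5 (0.117) and Mcm4 (0.115). They were also lost without untreated CD24hi replicate 2 for Lct (0.0664), Trpm5 (0.0835) and Mcm4 (0.0685) and without untreated CD24lo replicate 1 for Mcm4 (0.0665), adjusted p in parentheses. Over the 10 comparisons other than those of a response between the 2 fractions, 98 of 250 list tests passed with the preset correlation and 7 with an estimated one. The latter were MHC class II after Lgr5 ablation in both fractions and in irradiated CD24hi cells, p53 targets in irradiated cells of both fractions and in CD24hi cells after doxorubicin, and tuft genes in CD24hi cells with NICD. The median, mean and test direction of a list differed in sign in 19 of the 250, and all 19 lay short of the threshold.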

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

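For the planned tests, the second gene lists and bounds were written before their values were seen. Chosen only after the result was seen were the fits without the NICD CD24hi array that stood apart and the average over conditions without NICD. So were the list results without each array. The same holds for the second lists in CD24hi cells after doxorubicin and with NICD, and of T cell genes after Lgr5 ablation. The 4 differences between the fractions in their response to a treatment were tested directly, as interactions.

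Clca1 recurred in 3 of these tests. Its response was more positive in CD24hi than in CD24lo cells by 1.60 after Lgr5 ablation, where 2 genes passed, by 1.72 after irradiation, where it was the 1 gene that passed, and by 1.89 after doxorubicin, where 4 genes passed. All 3 differences share the 4 untreated arrays and are not independent. There Clca1 measured 14.03 and 14.29 in CD24lo and 11.96 and 11.88 in CD24hi cells. The former lie near the scale's top, so a ceiling stays open. The calls did not hold without untreated CD24lo replicate 2, where Clca1 gave adjusted p = 0.363, 0.49 and 0.132 in that order, or without untreated CD24hi replicate 1, where it gave 0.144, 0.218 and 0.0769, and further arrays ended them as given in the report. AW112010 differed by 2.78 after Lgr5 ablation and kept its call without any 1 array. After doxorubicin Mmp7 differed by 2.32, Defa39 by 2.24 and Stil by 2.13, and each lost its call without untreated CD24lo replicate 2, with adjusted p = 0.132 for each.

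The response to NICD differed between fractions for 314 genes. A more positive response in CD24hi cells was seen for the enterocyte genes Apoa4 at 4.05, Lct at 3.75, Apoc3 at 3.68 and Apoa1 at 3.48, the tuft cell genes Trpm5 at 3.12, Siglecf at 3.01, Dclk1 at 2.46 and Avil at 2.24, and the enteroendocrine hormone genes Cck at 3.15, Gip at 2.25 and Sct at 2.16. The same held for the keratin genes Krt19 at 1.60 and Krt8 at 1.17, the cell cycle inhibitor gene Cdkn1a at 2.12, and for Dgki at 4.70, the antibody gene Ighg3 at 4.61 and the glucose phosphatase gene G6pc at 4.07. A more negative response was seen for the S phase genes Mcm4 at -1.58 and Slbp at -1.27, and for the chemokine receptor gene Ccr2 at -3.73, Clca3a2 at -3.35, Ripor2 at -2.88, Tubgcp5 at -2.76 and Casp8ap2 at -2.64. Each of these 24 genes lost its call without at least 1 array. The total was 0 without NICD CD24lo replicate 2 in limma, with 1850 genes at an unadjusted p below 0.05, and 2622 without NICD CD24hi replicate 1, so this difference rests on single arrays.

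The first pattern weighed was the rise of leukocyte genes in sorted cells. In CD24lo cells with NICD, Ptprc measured 11.66 and 12.16 against 6.07 and 8.92 in untreated cells. A second list of T cell genes, 10 of 25 measured and none in the first, had 7 past the threshold. Its median change was 1.59 (bootstrap interval over genes, not arrays, 0.59 to 2.44). A second list of mast cell genes, 4 of 12 measured, had a median of 0.84 (0.51 to 1.98), just above the bound of 0.5, though other gut cells also make Kit and Hdc, and the macrophage gene Mpeg1 differed by 3.19 ± 0.75. Leukocytes of unknown kind in the gate may explain these genes. So may a change within sorted cells, which was not tested. The calls rest on NICD CD24lo replicate 2. In CD24lo cells after doxorubicin Gzma measured 10.36 and 10.39 against 6.77 and 7.02, but the second T cell list had a median of 0.49 (-0.14 to 1.09) with 7 of 10 genes higher and 1, Klrd1, past the threshold, so T cells and a change within the sorted cells cannot be told apart there, the interval spanning the bound. Nor can they in CD24hi cells, where the second T cell list had a median of 0.44 (0.042 to 0.63) after doxorubicin and 0.83 (0.11 to 1.47) with NICD, with Rac2 at 3.38 past the threshold in the latter and both intervals spanning the bound, and a gate against CD45 would remove such cells.

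The second pattern was the rise of pancreatic acinar genes. Cel measured 9.02 and 7.29 in irradiated CD24hi cells against 4.55 and 4.81 in untreated ones, and 8.13 and 6.47 in CD24lo cells after doxorubicin against 4.63 and 4.99. A second list of acinar genes, 4 of 14 measured, had a median of 0.49 (0.39 to 1.48) after irradiation, with 4 higher and 0 past the threshold in limma, and 0.95 (-1.41 to 1.78) after doxorubicin, where Spink1 differed by 1.78 ± 0.54 and Rnase1 by -1.41 ± 0.32, genes that the gut can also express, and 0.34 (-0.26 to 1.57) in CD24hi cells after doxorubicin. Acinar cells or their RNA and a change within the sorted cells cannot be told apart from these values, because 4 genes are too few and the 3 intervals span the bound of 0.5. Mist1 is itself made by acinar cells, so the TdTomato gate would not remove them, and a stain for an intestinal surface protein would.

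The third pattern was the rise of MHC class II genes after Lgr5 ablation, where H2-Aa measured 11.67 and 12.16 in CD24lo and 11.97 and 12.02 in CD24hi cells. Antigen-presenting cells in the gate would bring their other genes. A second list had 10 of 18 measured, with Ctss and Irf8 that epithelial cells can also make. In CD24lo cells its median was -0.26 (-0.65 to 0.45, resampling genes, not arrays), with 4 of 10 higher. This argues only weakly against that source. In CD24hi cells the median was 0.24 (-0.32 to 0.56) with 8 of 10 higher, and since the interval reaches past 0.5, such cells and a rise within the sorted cells cannot be told apart. The T cell list rose too, and T cells cannot be told apart from a change within the sorted cells there, since its second list had medians of 0.13 (0.0070 to 0.57) in CD24lo and 0.34 (0.14 to 0.59) in CD24hi cells, with no gene past the threshold and both intervals spanning the bound. A response of epithelial cells to ablation or DT may explain the MHC class II rise in CD24lo cells. This hypothesis was found and read on the same data. A stain for the protein on EpCAM-positive, CD45-negative sorted cells would test it.

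Whether chance could give the differences between the sorted fractions was tested by 100 splits of the arrays within conditions. Chance can be excluded for the number of genes that differed over all conditions, since the 5529 genes of the real split were reached by 1 of 100 splits, itself, and the highest other split gave 1550. Chance cannot be excluded for the 7 gene lists called, since 57 of 100 splits gave as many, the highest other 13. Some splits keep part of the real split.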

How the results depend on the processing

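The tests chosen only after the result was seen were the fits without the array that stood apart, the average without NICD, the list results without each array, and the second lists in CD24hi cells after doxorubicin and with NICD and of T cell genes after Lgr5 ablation. Outside leave-one-out, 132 of 165 counts lay within 1.5 times the reported one, 22 were lower and 11 higher. For named genes past the threshold, 8206 of 9491 values kept direction and call, 1282 kept only the direction and 3 had the opposite one. Of 503 such results 344 kept their call under each alternative other than leave-one-out. Those reversed were the NICD difference of Ccr2 at 0.22 with no filter, by way of another probe set, and in CD24lo cells with NICD, Mcm3 at -0.17 and Ramp1 at 0.021 with the mean of probe sets, since 4 of 5 and 2 of 3 of their probe sets went the other way.

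For genes with a different response to treatment in the 2 fractions, the cause of a moved count was not tested unless given. For Lgr5 ablation the count of 2 became 1 with a pseudocount of 1, 75th percentile centring, no filter, no trend, the replicate block, or only the groups compared, and 4 with quantile normalization. For irradiation the count of 1 became 2 with a pseudocount of 64, and 0 in limma with no filter, the mean of probe sets, the block or only the groups compared, where 669, 542, 412 and 421 genes had an unadjusted p below 0.05. For doxorubicin the count of 4 became 10 with a pseudocount of 1 or 64 or the mean of probe sets, 7 with quantile normalization, 9 with the stricter filter or robust settings, 1 with centring, no filter or the block, 64 with only the groups compared, and 12 without the array that stood apart. For NICD 314 became 56 with no filter, 42 with no trend, 199 with the block and 74 with only the groups compared. Fitting only the groups compared gave 0 genes for Lgr5 ablation in CD24lo cells (485 at an unadjusted p below 0.05) and 33 in CD24hi cells, 221 for irradiated CD24lo cells, 406 for CD24hi cells after doxorubicin, and 861 and 456 for NICD in CD24lo and CD24hi cells.

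With 1 array left out, counts ran from 868 to 1285 for untreated fractions, 4964 to 5679 for all conditions, 12 to 46 and 36 to 186 for Lgr5 ablation in CD24lo and CD24hi cells, 112 to 322 and 163 to 530 for irradiation, 394 to 1440 and 26 to 82 for doxorubicin, and 4 to 1741 and 206 to 2238 for NICD. Differences between fractions ran from 1 to 26 for Lgr5 ablation, 0 to 2 for irradiation, 0 to 8 for doxorubicin and 0 to 2622 for NICD. Where limma gave 0, the genes at an unadjusted p below 0.05 numbered 283 to 583 for irradiation, 840 to 1036 for doxorubicin and 1850 for NICD. List calls fell from 129 of 350 to 7 with an estimated correlation, which allows for genes that move together. Quantile normalization kept 314 of 350 list results and the block 346. For whole intestine, quantile normalization of 21 arrays moved 40 of 50 list medians, the enterocyte one against CD24lo cells from 2.44 to 1.98, and a pseudocount of 64 moved 21. Residuals of arrays with the same number correlated across genes from -0.149 to 0.385 between fractions and from -0.400 to 0.214 between treated and untreated.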

Other observations

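The tests here were planned, and the genes of the first paragraph were chosen after their values were seen.

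Gsdmc2 was among the genes with the largest falls after several injuries. It measured 10.23 and 10.36 in untreated CD24lo and 7.14 and 7.55 in untreated CD24hi cells. In CD24lo cells it fell by 6.23 ± 0.38 after irradiation, fell by 5.91 ± 0.38 after doxorubicin and fell by 2.96 ± 0.38 after Lgr5 ablation. In CD24hi cells it fell by 3.27 ± 0.38 after irradiation and fell by 3.13 ± 0.38 after doxorubicin, and all 5 calls held without any 1 array. The irradiated arrays stood between 4.04 and 4.10 in CD24lo cells, near the floor of the scale, where folds are understated. Mbl2, a lectin that binds mannose, rose in CD24lo cells by 4.88 ± 0.46 after irradiation and by 4.05 ± 0.46 after doxorubicin, also without a loss of call when 1 array was left out.

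Whole intestine, 1 sample without a test, had a median signal of 62.7 against 101 to 158 on the sorted arrays. Random lists matched on expression had median differences from untreated sorted cells of -1.15 to 0.44 rather than 0, against which the following values are to be read. The median difference of enterocyte genes was 2.44 against CD24lo and 4.82 against CD24hi cells, of T cell genes 4.01 and 4.23, and of Reg family genes 1.28 and 2.46. Paneth genes differed by -2.49 and -3.55, goblet genes by -2.73 and -1.87, stem cell genes by -2.19 and -3.66, S phase genes by -1.99 and -2.26, and G2/M genes by -2.55 and -2.19. Bhlha15 differed by -3.49 and -5.59, Lgr5 by -2.30 and -4.84, and Olfm4 by -2.67 and -3.65. Tuft genes differed by 1.03 and -0.06, against -0.87 and -1.07 for random lists, and interferon genes by 0.59 and 1.76. With quantile normalization of the 21 arrays the tuft differences were 1.54 and 0.86, the second of opposite sign, and those of S phase genes were -1.26 and -1.55.

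Lists were also tested for a different response of the 2 fractions. With the preset correlation, 10 lists passed for Lgr5 ablation, 6 for irradiation, 8 for doxorubicin and 7 for NICD, and with an estimated correlation 0 passed by limma's camera, the lowest adjusted p being 0.269, 0.19, 0.0914 and 0.274, with 1, 2, 4 and 1 lists at an unadjusted p below 0.05.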
